A study of Macaca mulatta with 1631 samples.

How the data were processed

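Gene expression was measured in single memory CD4 T cells sorted from 2 rhesus macaques (Macaca mulatta) during acute infection with simian immunodeficiency virus (SIV). Cells of animal T034 came from blood (PBMC, peripheral blood mononuclear cells) and cells of animal AY69 from a lymph node, so animal and tissue were confounded throughout. Per the labels' protocols, each cell was lysed in a well of a 96-well plate and its cDNA was made by SMART-Seq with a kit for very low RNA input, a full-length method without molecular identifiers.

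The deposited values were counts: whole numbers of reads per Ensembl gene and well, not normalised, in 1 table per animal. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, HTSeq 0.9.1 and the genome build Mmul_8.0.1, without roles or order. The annotation version, the filters applied before deposit and whether counting used strand are not given in the sources used here. Each table held 20618 host genes, 92 ERCC spike-in transcripts (synthetic control RNA) and 1 viral entry. Spike-in and viral counts were left out of host library sizes and tests. Every column matched the title of 1 sample. A reference table of gene names gave a symbol to 14603 of the host genes, and these genes held 76.6% of host counts. Of 505 entries in the gene lists, 377 were matched, and JUN, CD3D and CD2 were among those not matched. Reads shared between members of gene families, such as the APOBEC3 and IFIT genes, the histone gene H2BC5, HBA, and RPS4Y1 with RPS4Y2, could have been split or lost by the counting, so values of these genes are uncertain.

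Wells were grouped by the labels alone. A single-cell well was assigned to no SIV RNA, to SIV RNA without the tat-rev junction, or to SIV RNA with the tat-rev junction, the splice junction of transcripts for the viral regulators Tat and Rev. Labels for a second junction, D1-A5, and for SIV above 1% served as alternatives. Of 1631 wells, 1598 held single cells, and 1558 of these passed a filter of at least 50000 host counts and 500 host genes with a count, while 40 did not. A stricter filter of 200000 host counts and 1000 host genes kept 1484 wells. No clustering was done and no doublet caller was run, since each cell had been sorted into its own well through a single gate. Empty wells and pools of 1000 cells were described and not tested.

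The choices in this paragraph and the next were made before the data were examined. Cells are not replicates, so counts were summed over the passing wells of each animal and state. The 6 sums were fitted with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM factors and the animal as a block. The pairing comes from the labels, which name the same animal for wells of every state. All 3 states shared an estimate of the spread, which left 2 residual degrees of freedom, 2.565 prior degrees of freedom and a common dispersion of 0.4153. A gene was tested if it had a count in at least 5% of the passing wells of a state in each animal and passed filterByExpr with a minimum count of 10, which left 7691 genes, 6111 of them with a symbol. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. Standard errors of edgeR folds were approximated from the fold and its F statistic. CPM values are counts scaled to a common library total. Those of sums use TMM library sizes, except for AP-1 genes and the blood and lymph node values, which use plain host totals.

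Of 27 gene lists, the 19 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with 57 tests adjusted together. They were the AP-1 family, immediate early and stress response, NF-kB response, interferon-stimulated, restriction factors, T cell activation, cell cycle, follicular helper, regulatory T cell, central memory and quiescence, virus entry and homing receptors, T cell receptor complex and signalling, MHC class I presentation, p53 targets, transcription elongation, glycolysis, oxidative phosphorylation, unfolded protein response and ribosomal proteins. The other 8 had too few tested members and were only described: immune checkpoints, Th1 and cytotoxic, Th17, cholesterol synthesis, B cell, myeloid, NK and CD8 T cell, and red cell and platelet markers. The 19 lists were also tested with an estimated correlation, for which camera uses the residual degrees of freedom. With only 2 of these on sums, calls can be lost there without any correlation between genes. Genes were named by rule: up to 10 with the largest fold each way among genes with a symbol that passed with the same sign in both animals, or the 5 with the smallest p where none passed, plus the AP-1 genes and up to 4 members of each list with the smallest p.

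Shares of wells are given with 95% Clopper-Pearson intervals. For shares of cells with an AP-1 transcript, each passing well was thinned to 50000 host counts, a number that every passing well reached. Where a gene had 0 counts, a floor of 3 counts over the group gave the bound on its level. Where 0 wells of a group had a count, the upper bound of the share was 3 divided by the number of wells. This bound is not the Clopper-Pearson limit and is rough for few wells. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Blood and lymph node were compared by the log2 ratio of CPM in wells without SIV RNA, for 2937 genes with a count in at least 20% of the passing wells of an animal. List medians were set against 10000 random lists of the same size matched on mean expression. Pools were compared with the sum of the single cells of their plate by the correlation across genes of log2(CPM + 1).

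For each comparison, 16 alternatives with a count of called genes were fixed before the data were examined, among them DESeq2 1.42.0, other filters on wells and genes, other definitions of the states, thinned wells, no block, and sums per plate and state. A further 6 were added after seeing the data. The main added alternative takes the mean of log2(CPM + 1) over the wells of each plate and state, which gives every cell the same weight, and fits these 51 means with limma, weighted by the number of wells, with the plate as a block. It is called the test on plate means. It was chosen after the results of the main test and of the plate sums had been seen. Plates of 1 animal are not independent animals, so its p-values measure only the spread between plates of these 2 animals, and differences on the log2(CPM + 1) scale understate folds of genes with low counts but exceed the fold in level where the share of cells with a count changes. Genes from it are named by the same rule of 10 each way. Some genes that the rules select are not reported here.

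The tests were tested on simulated counts, with 200 genes changed in each state with SIV RNA. For sums, counts were drawn from the real means and library sizes, with a dispersion that depended on the mean alone. For plate means, each gene was drawn separately from real wells without SIV RNA. Neither keeps the correlation between genes, and that for sums does not keep genes whose counts sit in single wells. False calls may thus be more frequent in the real data. For SIV RNA with tat-rev against no SIV RNA, the edgeR test on sums (7690 genes) called 0%, 25.8% and 40.3% of genes changed by 1, 2 and 3 on the log2 scale, and 1 of 7491 unchanged genes. The test on plate means (7691 genes) called 0%, 9.7% and 12.9%, with median differences of 0.19, 0.37 and 0.42 for those sizes, and 1 unchanged gene. For SIV RNA without tat-rev, the test on sums called 3%, 11.5% and 43.6%, and for with against without tat-rev it called 3.5%, 22.9% and 42.7%. Descriptive values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.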

Results

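Transcript counts were obtained from sorted memory CD4 T cells of 2 rhesus macaques in acute SIV infection. Blood cells of animal T034 filled 10 plates and lymph node cells of animal AY69 filled 7 plates. Among the single-cell wells of T034, 777 had no SIV RNA, 105 had SIV RNA without the tat-rev junction and 59 had SIV RNA with it. The corresponding numbers in AY69 were 408, 150 and 99. There were also 19 empty wells on the plates of T034, and 7 empty wells and 7 pools of 1000 cells on those of AY69. In the wells that passed the filter and had no SIV RNA, the median was 5625700 host counts (range 101326 to 15670019) on 1494 genes in T034 and 1589450 host counts (117771 to 4728417) on 2073 genes in AY69. Wells of the other states were of similar depth. The medians were 5422440 counts and 1475 genes without tat-rev and 5440150 counts and 1404 genes with tat-rev in T034, and 1585930 counts and 2157 genes and 1532260 counts and 2129 genes in AY69.

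To determine how often cells carried viral transcripts, wells were counted by label. SIV RNA was present in 249 of 657 single-cell wells of AY69, or 37.9% (95% interval 34.2 to 41.7%), and in 164 of 941 wells of T034, or 17.4% (15.1 to 20.01%). The tat-rev junction was seen in 15.1% (12.4 to 18.0%) and 6.27% (4.81 to 8.01%) of wells. The share of wells with SIV RNA varied over plates from 29.8 to 54.3% in AY69 and from 10.6 to 25.5% in T034. With 1 animal per tissue, the difference between animals was not tested.

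Viral counts followed these labels. In wells with tat-rev, the viral entry took a median of 9.94% of counts in AY69 (range 0.0181 to 38.7%) and 6.91% in T034 (1.73e-05 to 34.7%, where the lowest well held 1 viral count). In wells with SIV RNA but without tat-rev, the medians were 0.0605% and 0.0134% over all wells and 0.0621% and 0.00548% over those that passed the filter. The 408 and 777 wells labelled as without SIV RNA held no viral count, which that label implies. None was found in the 7 and 19 empty wells either, which allows shares of up to 42.9% and 15.8%. Wells with tat-rev also carried the label for SIV above 1% in 92.9% (AY69) and 91.5% (T034) of cases, against 5.33% and 15.2% of wells without tat-rev. The D1-A5 junction was seen in 97.0% and 74.6% of wells with tat-rev and in 6 of 150 and 4 of 105 wells without.

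The title of the series names AP-1, a family of dimeric transcription factors, and its member c-Fos, encoded by FOS. FOS transcripts were therefore compared between states in each animal. In AY69, FOS was detected in 91.8% of cells without SIV RNA (88.7 to 94.3%), in 91.8% of cells with SIV RNA but no tat-rev (86.2 to 95.7%) and in 79.8% of cells with tat-rev (70.5 to 87.2%), after thinning to 50000 counts. In T034, the shares were 60.9% (57.3 to 64.4%), 54.1% (43.7 to 64.2%) and 55.9% (42.4 to 68.8%), a difference within the counting intervals. Without thinning they were 92.1%, 92.5% and 79.8% in AY69 and 67.1%, 61.2% and 61.02% in T034. Mean FOS levels over cells were 5657, 5586 and 2884 CPM in AY69 and 3420.0, 2269 and 819 CPM in T034. JUNB, a partner of FOS in AP-1, was detected in 76.0%, 72.1% and 73.7% of cells in AY69 and in 32.9%, 32.7% and 27.1% in T034, with mean levels of 862, 918 and 492 CPM and of 325, 234 and 188 CPM. JUND was detected in 61.1%, 62.6% and 59.6% of cells in AY69 and in 50.2%, 41.8% and 44.1% in T034. FOSB was detected in 19.1%, 16.3% and 10.1% of cells in AY69 and in 7.72%, 8.16% and 11.9% in T034. FOSL2 was detected in 3.47%, 2.04% and 3.03% of cells in AY69 and in 7.19%, 5.10% and 8.47% in T034.

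**Figure D1:**
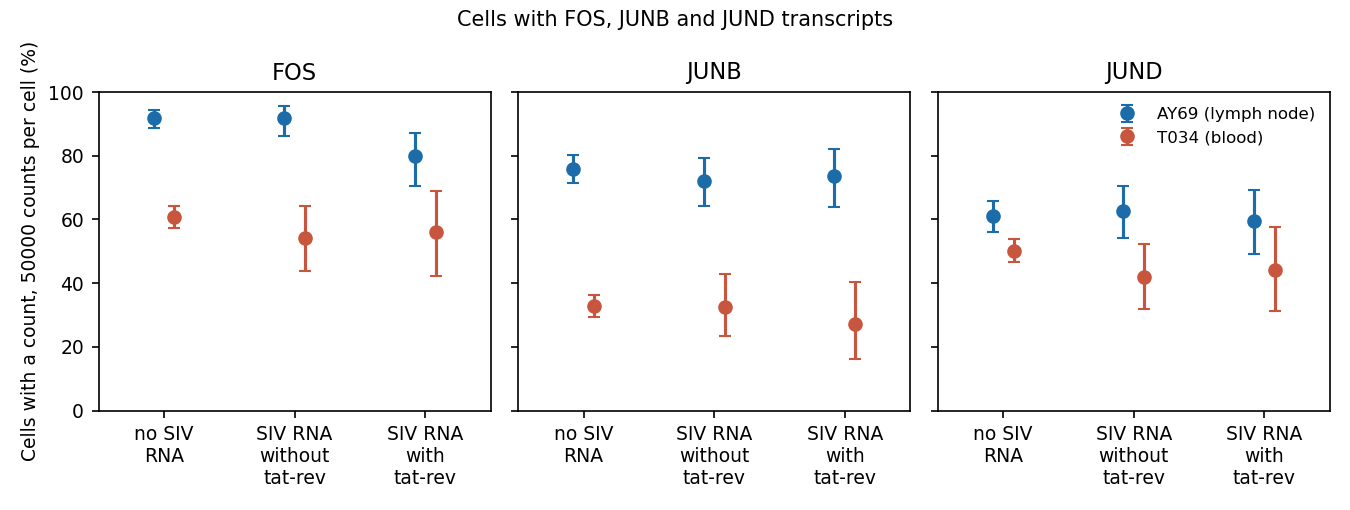
Share of cells (%, y axis) with at least 1 count of FOS, JUNB or JUND after thinning each cell to 50000 host counts, by SIV state (x axis), in AY69 (lymph node) and T034 (blood); bars are 95% Clopper-Pearson intervals. FOS was detected in 79.8% of AY69 cells with tat-rev, with an interval below that of cells without SIV RNA and overlapping that of cells without tat-rev. In T034 all intervals overlapped.

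In the edgeR test on sums, the FOS fold was -1.56 (log2, SE 0.29, adjusted p = 0.914) with tat-rev against no SIV RNA, with -0.99 in AY69 and -2.13 in T034, and did not pass. It was -0.33 without tat-rev against no SIV RNA and -1.23 with against without tat-rev. JUNB folds were -0.93, -0.17 and -0.76, and JUND folds -0.26, -0.14 and -0.12. FOSB folds were -0.06, -0.09 and 0.02, the last of which was negative on plate means (-0.23). On plate means, where each cell counts alike and which were tested only after the sums had been seen, FOS fell in cells with tat-rev against no SIV RNA by 1.91 (SE 0.38, limma adjusted p = 0.00641). The difference was -2.21 on the plates of AY69 (adjusted p = 0.00886) and -1.38 on those of T034 (adjusted p = 0.498), and the difference between the animals did not pass its own test (limma interaction adjusted p = 0.865). FOS differed by -0.64 without tat-rev against no SIV RNA and by -1.27 with against without tat-rev, with limma adjusted p of 0.683 and 0.292. JUNB was not called on plate means (-0.63, limma adjusted p = 0.442).

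Cells with the tat-rev junction were set against cells without SIV RNA to find which host transcripts differed where spliced viral transcripts were seen. On plate means, a test chosen after that on sums had been seen, transcripts of PECAM1, an adhesion molecule, fell by 1.90 (SE 0.30), and those of S1PR1, the sphingosine-1-phosphate receptor used to leave lymph nodes, by 1.39 (SE 0.27). Their limma adjusted p-values were 0.000565 and 0.00641. PTGER4, a prostaglandin E2 receptor, fell by 1.46, the lysosomal enzyme gene PPT1 by 1.36, RPL10A, a ribosomal protein, by 1.32, ESYT1 by 1.20, LYST by 1.19 and EIF4E2 by 1.13. Transcripts that rose included the interferon-induced IFI44 (1.99, SE 0.46, limma adjusted p = 0.0227), BST2 (1.61, SE 0.40, adjusted p = 0.0367), which encodes tetherin, a protein that holds virions at the cell surface, and APOBEC3H (1.65, SE 0.41, adjusted p = 0.0367), a cytidine deaminase that acts on retroviruses. CD3G, a chain of the T cell receptor complex, rose by 1.78, the adaptor HCST by 1.74, the p53 target RPS27L by 1.63, CHTOP by 1.58, the receptor SIRPG by 1.55, TMEM50A by 1.53 and TXNIP, which encodes an inhibitor of thioredoxin, by 1.52. On sums the folds of these 10 genes were smaller, from 0.22 for TXNIP (-0.18 in T034) to 0.85 for CHTOP, and none passed (edgeR adjusted p = 0.914).

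In all, 75 of 7691 genes were called on plate means, 43 higher and 32 lower, and 59 of them had a symbol. All 75 had the same sign on the plates of both animals, which is partly due to their selection on both together. On the plates of T034 alone 13 genes were higher and 22 lower, and on those of AY69 alone 19 were higher and 20 lower, and of the 75 genes these held 10 and 16. CD79A, a B cell marker, was among the lower genes (-0.50, limma adjusted p = 0.0261). It was detected in 7.43% of AY69 cells without SIV RNA and 4.04% with tat-rev, and in 8.26% of T034 cells without SIV RNA and 0 of 59 with tat-rev, which allows up to 5.08%. Whether the states differed in cell make-up, such as in other cells that the sort gate could hold, was not tested. Transcripts said here to rise or fall therefore need not have changed within cells of 1 kind.

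**Figure D2:**
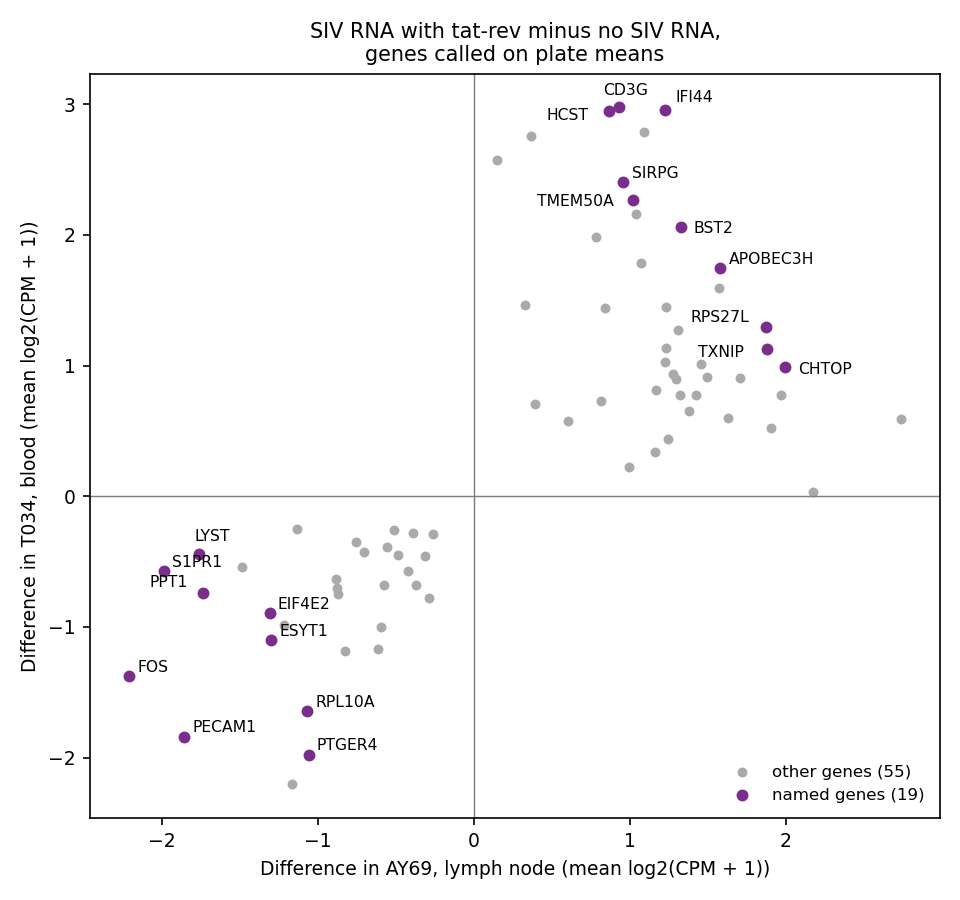
Each point is 1 of 74 of the 75 genes called by limma on plate means for SIV RNA with tat-rev against no SIV RNA, with the difference of mean log2(CPM + 1) on the plates of AY69 (x axis) and of T034 (y axis); the 19 named genes are in purple. All 74 points, selected on both animals together, lie in the quadrants where both animals have the same sign.

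The edgeR test on the 6 sums, which was the test fixed in advance, called 1 gene, lower with tat-rev, and 330 genes had an unadjusted p under 0.05. This gene, ENSMMUG00000046927, has no symbol here, and its fold was -5.17 (log2, SE 0.17, adjusted p = 0.0137). It was detected in few cells, and in more of those with tat-rev (11.1% in AY69 and 10.2% in T034) than of those without SIV RNA (4.70% and 8.79%). A single well held 62.7% of its counts in AY69 cells without SIV RNA. On plate means this gene differed by 0.20 in the other direction (limma adjusted p = 0.698). No gene with a symbol passed, and those with the smallest p included CD74, TUFT1, MARCKS and ZNF682.

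CD74, the invariant chain of MHC class II, had a fold of -1.66 on sums (SE 0.15, edgeR adjusted p = 0.442), but a difference of -0.10 on plate means (limma adjusted p = 0.935). The folds of TUFT1 (-8.96), MARCKS (-6.24) and ZNF682 (-4.59) had an edgeR adjusted p of 0.914. TUFT1 had 6 and 2 counts with tat-rev in AY69 and T034, and a single well held 93.7% of the ZNF682 counts of AY69 cells without SIV RNA. MARCKS had 14 and 58 counts with tat-rev, though its detection in T034 was 52.5% of cells with tat-rev and 52.9% of those without SIV RNA. DESeq2 on the same sums called 25 genes higher and 56 lower, of which 16 were among those called on plate means. Limma on means per animal and state called 0 genes (684 with an unadjusted p under 0.05). With 2 animals, of different tissues, the spread between animals of 1 tissue was not measured.

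Gene lists were tested next. Interferon-stimulated genes rose with tat-rev as a list (camera adjusted p = 2.74e-07), a call that was lost on estimating the correlation (adjusted p = 0.624 with an estimated correlation). Of 31 tested members 24 had a positive fold, with a median of 0.29. Single members did not pass in the edgeR test, with 0 over all genes and 0 adjusted over the list alone. Those with the smallest p were IFIT3 (0.76), PARP9 (0.96), OAS3 (0.70) and IFI44 (0.73). On plate means 4 members rose over all genes, IFI44 (1.99), IFIT3 (1.37), PARP9 (1.11) and IFIT5 (1.27, named after its value was seen), and 11 rose adjusted over the list alone by limma. The restriction factor list, cellular genes that act against retroviruses, had a camera adjusted p of 0.0563, with 8 of 12 members positive and 0 past the edgeR threshold over all genes or adjusted over the list alone. On plate means 2 of its members, BST2 and APOBEC3H, rose over all genes, and 3 rose adjusted over the list alone.

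Genes of central memory and quiescence, which mark recirculating resting T cells, fell as a list (camera adjusted p = 3.47e-08). The call was lost on estimating the correlation (adjusted p = 0.624 with an estimated correlation), although that correlation (-0.0546) was below the preset 0.01. Camera then had only the 2 residual degrees of freedom of the sums. Of 14 tested members 13 had a negative fold, with a median of -0.96. No member passed the edgeR test over all genes, and 2 passed adjusted over the list alone. Members with the smallest p included S1PR1 (-2.32, SE 0.47), LEF1 (-0.89) and KLF2 (-0.79). On plate means the members that fell over all genes included S1PR1 and CCR7, a chemokine receptor for lymph node entry (-1.07, named after its value was seen), while TXNIP rose by 1.52, and adjusted over the list alone 6 members fell and 1 rose. With plate means and an estimated correlation the list tests of interferon-stimulated genes (adjusted p = 0.0330 with an estimated correlation) and of central memory genes (adjusted p = 0.00182 with an estimated correlation) still passed.

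Ribosomal protein genes fell as a list with tat-rev (camera adjusted p = 0.00454; adjusted p = 0.624 with an estimated correlation), with 34 of 37 members negative and a median of -0.21. The call was lost on thinned wells (camera adjusted p = 0.0897). Members with the smallest p, among them RPL10A (-0.69), RPL13 (-0.25) and RPL3 (-0.32), did not pass in edgeR, with 0 over all genes and 0 adjusted over the list alone, and on plate means only RPL10A fell. Follicular helper markers, with 5 of 5 members negative and medians of -0.21 in AY69 and -1.23 in T034, had a camera adjusted p of 0.0563. For the AP-1 family it was 0.264, with 5 of 8 members negative and 2, FOS and JUNB, past the edgeR threshold adjusted over the list alone. The other tested lists did not pass on sums. Their camera adjusted p was 0.139 for immediate early and stress response, 0.193 for T cell activation, 0.194 for NF-kB response and for T cell receptor complex and signalling, 0.233 for oxidative phosphorylation and for virus entry and homing receptors, 0.264 for p53 targets, 0.473 for MHC class I presentation, 0.645 for transcription elongation, 0.705 for regulatory T cell markers, 0.842 for glycolysis, 0.884 for cell cycle and 0.943 for unfolded protein response. Some lists that did not pass on sums per animal passed on plate means. T cell receptor complex and signalling genes (camera adjusted p = 0.0149) and restriction factors (0.0162) were higher there. Virus entry and homing receptors (0.0149) and follicular helper markers (0.0455) were lower. None of these lists passed with an estimated correlation (the smallest adjusted p = 0.0883 with an estimated correlation). On plate sums, T cell receptor complex and signalling genes (camera adjusted p = 0.00269) and restriction factors (0.00978) were also higher. With states reassigned at random, both lists pointed up in 8 of 8 reassignments, and passed as higher in 2 and 0 of them. Ribosomal protein and oxidative phosphorylation genes passed camera as higher in 8 of 8 reassignments. List tests on plate sums against no SIV RNA are therefore not read.

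Lists with fewer than 5 tested members were not tested, and their median folds with tat-rev against no SIV RNA are given as values. Immune checkpoints had a median of -0.54 over 3 genes (-0.15 in AY69 and -1.03 in T034). The medians of the 3 Th1 and cytotoxic markers were opposite in the animals, -1.46 in AY69 and 0.99 in T034, with no member of the same sign in both, and 0.99 on plate means. Of these, the cytotoxic granule gene NKG7 rose on the plates of T034 (3.78, limma adjusted p = 0.0158) and differed by -0.39 on those of AY69. Cholesterol synthesis genes had medians of -1.27 in AY69 and 0.52 in T034 over 3 genes, and 2 of 3 Th17 markers had a negative fold. The B cell list held only CD79A and the myeloid list only CD14, with folds on sums of -3.90 and -6.15 (-1.45 and -1.43 in AY69, edgeR adjusted p = 0.914 for both), whose size in T034 is set by 0 counts with tat-rev. CD14 was detected in 6.39% of T034 cells without SIV RNA and 0 of 59 with tat-rev, which allows up to 5.08%, and on plate means it differed by -0.14 (limma adjusted p = 0.337). No member of the NK and CD8 T cell list or of the red cell and platelet list was tested.

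**Figure D3:**
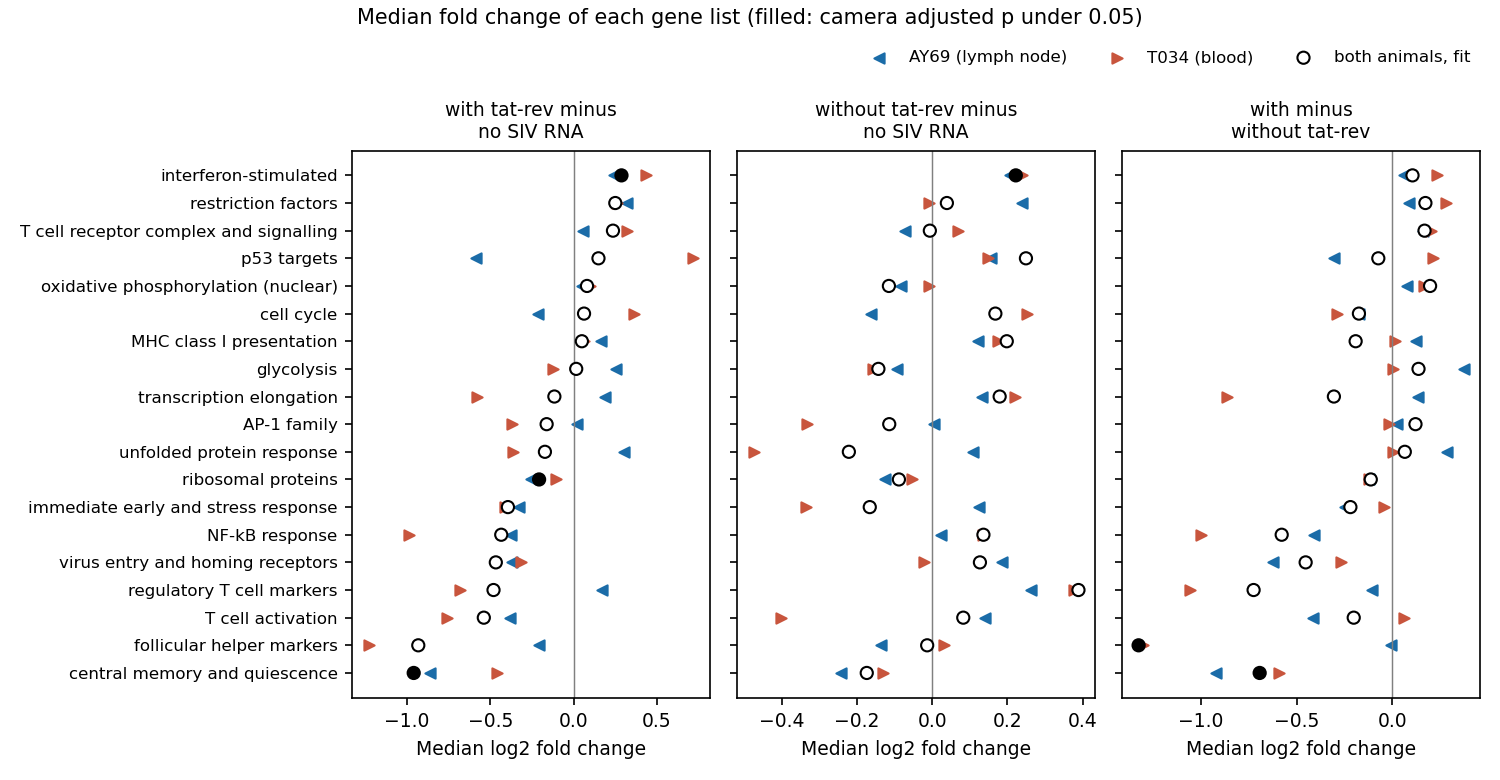
Median log2 fold change (x axis) of the tested members of 19 gene lists (y axis) in each of the 3 comparisons, from the edgeR test on sums (circles, filled where the camera adjusted p was under 0.05) and within AY69 and T034 (triangles). Filled circles mark interferon-stimulated genes in the first and the second panel, central memory and quiescence in the first and the third, ribosomal proteins in the first and follicular helper markers in the third.

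Cells with SIV RNA in which the tat-rev junction was not seen were compared with cells without SIV RNA to find host transcripts that differed in the absence of that junction. Interferon-stimulated genes rose as a list (camera adjusted p = 3.11e-07), with 29 of 31 members positive and a median fold of 0.22. This call, too, was lost on estimating the correlation (adjusted p = 0.624 with an estimated correlation), also on plate means (adjusted p = 0.211 with an estimated correlation). Members with the smallest p were IFIT3 (0.54), PARP14 (0.67), CMPK2 (0.68) and IFIT5 (0.72). Their folds were negative on plate sums, where reassigned states too gave 104 to 218 lower calls with edgeR. The other 18 lists did not pass, with camera adjusted p between 0.193 and 0.831. For central memory and quiescence it was 0.304, with 10 of 14 members negative and a median of -0.17, and for the AP-1 family 0.372, with 6 of 8 negative. On plate means ribosomal protein (camera adjusted p = 4.54e-06) and oxidative phosphorylation genes (0.0428) were lower and restriction factors higher (0.0179). No list passed there with an estimated correlation (the smallest adjusted p = 0.201 with an estimated correlation).

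No single gene passed the edgeR test, with 91 genes at an unadjusted p under 0.05, and 0 interferon-stimulated genes passed adjusted over the list alone. The smallest p belonged to CD74 (-1.58, SE 0.15), SGSH (-5.18), ZNF682 (-4.02), OXCT1 (-1.94) and KCTD1 (-4.71), with an edgeR adjusted p of 1 each. SGSH, a lysosomal sulfatase, had 22 counts in AY69 and 234 in T034 in cells without tat-rev. DESeq2 called 2 genes, and limma on means per animal and state 0 (133 with an unadjusted p under 0.05). On plate means NSDHL, an enzyme of cholesterol synthesis, fell by 0.44 (SE 0.07, limma adjusted p = 0.000231). It was detected in 6.68% of AY69 cells without SIV RNA and 2.04% of those without tat-rev, and in 5.46% of T034 cells without SIV RNA and in 0 of 98 without tat-rev, which allows up to 3.06%.

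To compare the states with viral RNA, cells with tat-rev were set against cells with SIV RNA but no tat-rev. Genes of central memory and quiescence were lower with tat-rev as a list (camera adjusted p = 2.55e-06), with 13 of 14 members negative and a median of -0.69. That call was lost on estimating the correlation (adjusted p = 0.624 with an estimated correlation) and on plate sums (camera adjusted p = 0.116). Follicular helper markers, which mark T cells that help B cells, were also lower (camera adjusted p = 0.0497). Of these, 5 of 5 had a negative fold, with a median of -1.32. Within the animals the median was -0.0092 in AY69 and -1.30 in T034, and 3 of 5 had the same sign in both. The follicular helper call was lost in the same settings (adjusted p = 0.624 with an estimated correlation, camera adjusted p = 0.0563 on plate sums). No member of either list passed in edgeR over all genes. Adjusted over the list alone, 1 central memory gene and 0 follicular helper genes passed. Values with the smallest p in these lists included S1PR1 (-2.13), CCR7 (-2.11) and FOXP1 (-0.65), and ICOS (-1.05), CXCR5 (-1.46), TCF7 (-1.32) and BCL6 (-1.90). TCF7 belongs to both lists. The fold of FOXP1 was positive on plate means (0.12), and those of CCR7 and FOXP1 were positive with states by SIV over 1%. With plate means and an estimated correlation, the central memory list still passed (adjusted p = 0.00674 with an estimated correlation), and the follicular helper list did not (adjusted p = 0.0883 with an estimated correlation). Its call was also lost on thinned wells (camera adjusted p = 0.0612). The other 17 lists had camera adjusted p between 0.139 and 0.962, with 0.552 for the AP-1 family, where the test pointed down and the median fold was 0.12, and 0.288 for interferon-stimulated genes. Of the AP-1 members, 0 passed edgeR over all genes and 2 passed adjusted over the list alone. Adjusted over the list alone on plate means, 1 AP-1 member was higher and 1 lower with limma. On plate means interferon-stimulated (camera adjusted p = 0.00275) and oxidative phosphorylation genes (0.0149) were higher and virus entry and homing receptors lower (0.0379), and none of these passed with an estimated correlation (the smallest adjusted p = 0.149 with an estimated correlation).

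Among single genes, PRR13 rose by 1.74 (SE 0.37) and B4GALT7, a glycosyltransferase, by 0.73 (SE 0.15) on plate means, while PECAM1 fell by 1.72 (SE 0.36), each with a limma adjusted p of 0.0360. B4GALT7 was detected in few cells. Without tat-rev it had a count in 5 of 147 cells of AY69 and 0 of 98 of T034, which allows up to 3.06%. With tat-rev these were 11 of 99 and 7 of 59. Plate means called 6 genes, 4 higher and 2 lower, of which 3 have no symbol here. With limma, neither animal's plates alone called a gene on plate means (580 and 653 genes with an unadjusted p under 0.05 in T034 and AY69), nor did thinned wells (720). The edgeR test on sums called 1 gene, again ENSMMUG00000046927 (-5.76, SE 0.17, adjusted p = 0.00957), with 407 genes at an unadjusted p under 0.05. Its detection was 5.44% and 11.1% of cells in AY69 and 3.06% and 10.2% in T034 without and with tat-rev, the reverse of the fold, and single wells held 99.7% (AY69) and 99.8% (T034) of its counts without tat-rev. With wells of under 10 viral counts left out, its fold was 3.05 and edgeR called 0 genes (352 at an unadjusted p under 0.05). The genes with a symbol and the smallest p included TUFT1 (-8.25), SYNE2 (-1.19), SGSH (5.18) and RPUSD4 (-5.47), with an edgeR adjusted p of 0.786 each. DESeq2 called 33 genes higher and 52 lower, 1 of them called on plate means.

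To ask whether cells without tat-rev differed from cells without SIV RNA in the same way as cells with tat-rev, the folds of both comparisons were set against each other. Among the 50 genes with the smallest p with tat-rev, 43 had the same sign without tat-rev, while random cells without SIV RNA in place of both states gave a median of 38 (range 32 to 44 over 100 draws), because the comparisons share control cells. With the control cells split so that none was shared, the median was 37 of 50 (34 to 42 over 20 splits), against 27 (19 to 35) for random cells. The correlation of folds across genes, which are not independent replicates, was 0.113 with shared controls, against 0.199 (0.153 to 0.245) for random cells, and the covariances were 0.142 and 0.248. With split controls the correlation was 0.038 in both cases, and the covariances were 0.0474 and 0.0505. The random cells were taken out of the cells without SIV RNA, so fewer control cells were left than with the real states. With shared controls this can raise the agreement of random cells. These values therefore do not tell whether the real agreement exceeded chance. The number of controls differed with split controls as well.

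Blood and lymph node cells without SIV RNA were described side by side, without a test, since each tissue came from 1 animal. The 10 genes with the highest ratio in the blood of T034 included the Y-linked genes RPS4Y1, UTY, RPS4Y2 and USP9Y, which had 0 counts in the 404 cells of AY69 and were at least 16.81, 14.82, 14.72 and 14.58 higher on the log2 scale. Y-linked DDX3Y (15.41) and EIF1AY (8.12), COL11A1 (6.997), the haemoglobin gene HBA (6.20), ALOX5AP (6.09) and GZMB (5.88), which encodes the cytotoxic protease granzyme B, completed these. The counts of Y-linked genes point to animals of different sex, so that sex, too, was confounded with tissue. GZMB was detected in 46.1% of T034 cells and 2.48% of AY69 cells. Some myeloid markers, named after their values were seen, were also higher in blood: LYZ (1835 against 4.22 CPM, in 11.7% and 0.495% of cells), S100A8 (327 against 1.08 CPM), TYROBP (115 against 12.5 CPM) and FCER1G (99.8 against 2.94 CPM), while CD68 was lower (0.661 against 4.74 CPM). The genes higher in the lymph node of AY69 were led by interferon-induced genes. IFIT1 had a log2 ratio of blood to lymph node of -5.35 and was detected in 5.46% of T034 cells and 82.4% of AY69 cells. RSAD2 (-4.34), OASL (-3.96), CMPK2 (-3.90), IFIT3 (-3.46) and OAS1 (-3.19) followed, together with GIMAP2 (-3.32), ERAP2 (-3.30), GPR171 (-3.17) and PLSCR2 (-3.05).

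The median log2 ratio of blood to lymph node of 31 interferon-stimulated genes was -1.88, at percentile 0 of 10000 random lists, and 1 of the 31 was higher in blood. T cell activation genes had a median of -1.28 (percentile 0.04), the AP-1 family -0.82 (percentile 1.02), restriction factors -0.60 (percentile 1.41) and MHC class I presentation genes -0.43 (percentile 4.34). Oxidative phosphorylation genes had a median of 0.28 (percentile 97.5), with 17 of 20 higher in blood. Other lists with at least 5 ranked members lay between percentiles 7.08 (central memory and quiescence) and 67.8 (cell cycle). These percentiles describe these libraries only.

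In AY69, each of 7 pools of 1000 cells was compared with the sum of the single cells of its plate. Host counts of the pools ranged from 974448 to 2555708, on 10330 to 11259 genes. The correlation across genes of log2(CPM + 1) was between 0.875 and 0.904, with a median of 0.884 ± 0.00904 (SD, n = 7). The viral entry took between 0.666 and 1.15% of counts in the pools and between 1.19 and 2.89% in the sums of single cells.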

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

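The tests of the difference between animals, of neural RNA, of too few viral counts for the junction and of reassigned plate sums, with their list tests, were chosen only after the results had been seen, while the tests of leaked T cell RNA and of viral counts leaked along plate rows and columns were written before their results.

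Of the 19 empty wells on the plates of T034, 10 lay at position H12, and these held 113035 to 195997 host counts on 4113 to 5327 genes. A median of 5.63% of their counts fell on 24 neural marker genes, against 0.0323% in single cells of the plates. SNAP25 was at 23788 CPM and MBP at 6698 CPM. MBP is also seen in T cells, at 172 CPM and in 30.0% of the single cells of T034. The markers THY1, MOG and MOBP had 0 counts in the wells at H12. RNA leaked from the T cells of the plate is argued against, since the share of T cell marker counts in these wells was at most 0.00507 of that in single cells, and CD3E, CD3G and LCK had 0 counts. A candidate explanation is RNA of neural tissue in these wells, whose neural share was at least 116 times that of single cells in each of the 10 wells; 3 of the 24 markers are also seen in at least 5% of the T cells, and the sort for memory CD4 T cells would not pass neural cells. What these wells received is not given in the sources used here, and no biological explanation was tested.

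Many cells held SIV RNA in which the tat-rev junction was not seen. Too few viral counts to catch the junction could account for most of them: 91.3% of such wells in AY69 and 77.1% in T034 held fewer viral counts than the 5th percentile of wells with the junction, 7472 and 19916 counts. It cannot be told apart from a state without the junction in these wells, and 13 of 150 and 24 of 105 wells lay above that level. Viral counts leaked from wells of the same row or column were tested on the 42 wells with under 10 viral counts, 9 in AY69 and 33 in T034, whose rows and columns had a mean log10 viral count of 4.87 against 5.04 for reassigned wells (one-sided permutation p = 0.799), which does not exclude a leak. Viral RNA without this splice product, the biological alternative that the labels name, stays open.

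On sums per plate and state, 750 genes were called with tat-rev against no SIV RNA, all of them lower. Sums over few wells, which miss transcripts present in few cells, are a likely explanation. When states were reassigned at random to the wells of each plate, 8 reassignments gave a median of 668 lower calls (546 to 739) and 0 higher ones, and 56.1% of the genes called with the real states had 0 counts in the sums with tat-rev. The sums with tat-rev held 2 to 20 wells and those with no SIV RNA 43 to 80. A lower level in cells with tat-rev is therefore not read from this test.

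The effect of tat-rev against no SIV RNA differed between AY69 and T034 for 9 of 7691 genes on plate means (limma interaction, adjusted p under 0.05), with 632 at an unadjusted p under 0.05. In the comparison without tat-rev limma called 0 (429 at an unadjusted p under 0.05), and with against without tat-rev 0 (512). S100A4, a calcium-binding protein, had a difference of -4.57 between the animals (-0.46 in AY69 and 4.11 in T034, limma adjusted p = 0.000249), and NKG7, a gene of cytotoxic granules, of -4.17 (-0.39 and 3.78, adjusted p = 0.0198). GPR183, a chemotactic receptor, had a difference of 3.24 (0.78 and -2.46, adjusted p = 0.0156), PI4K2B of 3.11 (2.22 and -0.90, adjusted p = 0.0093), OTUD5 of 2.15 (0.64 and -1.51, adjusted p = 0.0277) and the histone gene H2BC5 of 2.14 (2.17 and 0.03, adjusted p = 0.0277). The others were 3 genes without a symbol, with differences of -2.43, -4.02 and -3.41. On sums the folds were different, with -2.34 in AY69 and 0.58 in T034 for S100A4 and -1.46 and 0.95 for NKG7. They were -0.21 and -2.12 for GPR183, 0.70 and -2.20 for PI4K2B, 0.10 and -2.63 for OTUD5 and 1.70 and 1.01 for H2BC5. Tissue and animal stay open as sources of these differences, since each tissue came from 1 animal.

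Of 18 groups of values tested, 4 had a well far from the others, where chance gives about 1 in 20, and 3 of these were related measures of 1 well. The pool of plate 1 had 2555708 host counts (next 1502908), 11259 genes (next 10715) and a correlation with its single cells of 0.904 (next 0.887). Among the empty wells of T034 at position H11, that of plate 1 had 3839553 host counts (next 930213, lowest 16750), and these wells held counts on 36 to 156 genes. The empty well at position H2 of plate 1 of AY69 held 2267818 host counts on 1084 genes, while the other 6 empty wells of AY69 held 18 to 6092 counts.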

How the results depend on the processing

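All values on plate means, on plate sums of genes detected in at least 20% of wells and without wells of low viral count were alternatives chosen after seeing the data; the others were fixed beforehand. Counts are given for tat-rev against no SIV RNA, without tat-rev against no SIV RNA and with against without tat-rev, in this order, where the edgeR test on sums gave 1, 0 and 1. Without the animal as a block, and so without the pairing, edgeR again called 1, 0 and 1 (136, 41 and 214 at an unadjusted p under 0.05), and the same numbers came with RLE factors, thinned wells, no or a strict well filter, other definitions of the states and viral counts in library sizes. Leaving out T034 or AY69 left 1 animal and no residual degrees of freedom, so it gave folds with no test and no count.

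DESeq2 called 81, 2 and 85 genes. With filterByExpr alone edgeR called 0, 0 and 1 (522, 147 and 531 at an unadjusted p under 0.05), and with genes detected in at least 20% of wells 1, 0 and 0 (187, 38 and 210). At that filter ENSMMUG00000046927, the call on all sums, was no longer tested, and the 1 call was another gene. Limma on means per animal called 0, 0 and 0 (684, 133 and 804). Plate sums gave 750, 151 and 7 with edgeR, those of T034 alone 1625, 514 and 20, those of AY69 alone 0, 0 and 1 (510, 166 and 430), and those of genes detected in at least 20% of wells 12, 0 and 1 (189, 39 and 99). Plate means gave 75, 1 and 6 with limma, those of T034 alone 35, 14 and 0 (580 at an unadjusted p under 0.05 in the last), those of AY69 alone 39, 1 and 0 (653 in the last) and those of thinned wells 70, 1 and 0 (720 in the last). Of the 75 genes, 62 were among those called on thinned wells, 10 among those of T034 alone and 16 among those of AY69 alone. Leaving out wells without tat-rev and with under 10 viral counts gave 0, 0 and 0 (272, 87 and 352). These wells belong to neither state of the first comparison, where the fold of ENSMMUG00000046927 stayed at -5.18 and its edgeR adjusted p was 0.285. All 3 states share an estimate of the spread, so this call depended on wells outside the states compared. Of 57 list tests, camera called 6, but 0 with an estimated correlation, 16 on plate means and 3 on plate means with an estimated correlation. On sums the estimated correlation leaves camera 2 degrees of freedom, so these losses do not by themselves show correlated genes. The share of T034 cells without SIV RNA with FOS was 67.1% without thinning, and the median correlation of pools and single cells was 0.914 on the log2(CPM + 10) scale. The ribosomal protein list with tat-rev against no SIV RNA pointed up on plate sums (camera adjusted p = 0.228), as it did in 8 of 8 random reassignments of states, so its direction there is not read. The call of the central memory list in this comparison was lost on plate sums (camera adjusted p = 0.282), where 7 of 8 reassignments pointed it up. Except where stated, the cause was not tested.

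Folds of named genes that changed sign in an alternative with a test follow. Folds within 1 animal of the opposite sign, such as that of TXNIP in T034, are not listed here. With tat-rev against no SIV RNA, plate sums gave TXNIP -0.11 and OAS3 -0.43, and plate sums of T034 gave APOBEC3H -0.0625, IFIT3 -0.44, TXNIP -0.48, CHTOP -0.26, PARP9 -0.77 and OAS3 -1.77. Plate means of T034 gave FOSB 0.30 and KLF2 0.19. ENSMMUG00000046927 was at 0.18 on animal means, 0.20 on plate means, 0.37 on those of AY69 and 0.20 on those of thinned wells.

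Without tat-rev against no SIV RNA, plate sums gave IFIT3 -0.32, CMPK2 -1.29, IFIT5 -1.54 and PARP14 -0.025, those of T034 IFIT3 -1.14, CMPK2 -6.17, IFIT5 -9.71 and PARP14 -0.19, those of AY69 JUNB 0.14 and FOS 0.066, and those of genes detected in at least 20% of wells IFIT3 -0.19. FOSB was at 0.027 in wells whose labels agree, KCTD1 at 0.034 on plate means of AY69 and 0.0031 on those of thinned wells, and ZNF682 at 0.0049 on animal means, 0.0033 on plate means and 0.0396 on those of AY69.

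With against without tat-rev, states by SIV over 1% gave CCR7 0.15 and FOXP1 0.32. FOXP1 was at 0.12 on plate means, 0.19 on those of T034, 0.083 on those of AY69 and 0.26 on those of thinned wells. FOSB was at -0.042 without the block, -0.19 on plate sums, -1.17 on those of AY69, -0.17 on animal means, -0.0081 with the strict well filter, -0.0805 with states by either junction, -0.20 with states by SIV over 1%, -0.24 in wells whose labels agree, -0.23 on plate means, -0.56 on those of AY69 and -0.10 on those of thinned wells. JUND was at 0.0028 on plate means, 0.20 on those of T034 and 0.0475 on those of thinned wells. ENSMMUG00000046927 was at 2.40 on plate sums, 2.90 on those of T034, 3.38 on those of AY69, 0.45 on animal means, 0.45 on plate means, 0.36 on those of T034, 0.50 on those of AY69, 0.44 on those of thinned wells and 3.05 without wells of low viral count.

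Values of named genes under the alternatives were counted. A tested value was kept if its direction and side of the threshold stayed the same. Folds within 1 animal had no test. For genes not called on sums, such a fold was kept, whatever its sign, if it lay within the SD of both animals' folds from the main fold. Agreement between the animals is therefore not read from these counts. For 38 genes with tat-rev against no SIV RNA, 769 values were kept, 96 came past the threshold, 4 lost it, 2 without a test moved and 14, over 9 genes, changed sign. For 14 genes without tat-rev against no SIV RNA these numbers were 284, 9, 0, 1 and 17, over 9 genes, and for 20 genes with against without tat-rev 408, 15, 0, 1 and 29, over 5 genes. The median fold of all genes moved by under 0.1 with RLE factors, DESeq2, thinned wells and viral counts in library sizes. With 59 cells with tat-rev in T034, shares of cells are known only within wide limits, and genes detected in few cells rest on single wells in sums.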

Other observations

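The reassignments of states to wells were chosen as tests only after the calls on the real states had been seen.

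Genes of T cell identity were described by state, as the share of cells with a count after thinning to 50000 counts. CD3G was detected in 68.1% (95% Clopper-Pearson interval 63.3 to 72.6%) of AY69 cells without SIV RNA, in 73.5% (65.6 to 80.4%) without tat-rev and in 76.8% (67.2 to 84.7%) with tat-rev. In T034 the shares were 41.1% (37.6 to 44.8%), 56.1% (45.7 to 66.1%) and 69.5% (56.1 to 80.8%). Mean CD3G levels were 442, 501 and 588 CPM in AY69 and 381, 453 and 907 CPM in T034. CD3E was detected in 56.4%, 53.1% and 53.5% of AY69 cells and in 17.8%, 18.4% and 27.1% of T034 cells. CD4, which encodes the receptor that SIV binds, was detected in 18.6%, 21.1% and 22.2% of AY69 cells and in 4.53%, 7.14% and 5.08% of T034 cells, with mean levels of 64.5, 100.03 and 109.8 CPM and of 25.8, 30.7 and 45.9 CPM. Without thinning, CD3G was detected in 69.8%, 74.8% and 78.8% of AY69 cells and in 42.1%, 58.2% and 69.5% of T034 cells.

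States were reassigned at random to the wells within each plate, and the calls were counted again in 100 assignments with the real one among them. On plate means, the 75 genes called with tat-rev against no SIV RNA were reached by 1 of 100 assignments, the real one, and the highest other gave 3 genes. The 6 genes with against without tat-rev were likewise reached by 1 of 100, with a highest other of 4. In both cases 1 of 100 is the smallest share that these assignments can give. Random placement of wells is argued against for the number of 75 calls, though not for each gene. For the 6 calls it stays open, since another assignment reached 4 and plate means of thinned wells called 0. For NSDHL, the 1 gene called without tat-rev against no SIV RNA, 17 of 100 assignments called as many or more, up to 3, and chance cannot be excluded. In the edgeR test on sums, the 1 gene called with tat-rev against no SIV RNA was matched by 3 of 100 assignments, as was the 1 gene with against without tat-rev, with a highest other of 1 in both. In both comparisons the call was ENSMMUG00000046927. With against without tat-rev, 1 well held 99.8% of its counts without tat-rev in T034, and its fold was 3.05 without wells of low viral count, so the placement of a single well by chance stays open there. With tat-rev against no SIV RNA, such wells belong to neither state, but without them edgeR called 0 genes there too. In cells without SIV RNA, 1 well held 62.7% of the counts of this gene in AY69, and 1 well held 22.5% in T034. The placement of single wells by chance thus stays open in this comparison as well. The 0 genes without tat-rev against no SIV RNA were matched by 100 of 100, with a highest other of 0. Wells were reassigned within the same 2 animals, so these counts say nothing about other animals.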
